A study of Mus musculus with 6 samples.

How the data were processed

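Single-cell libraries were prepared from cells sorted out of mouse skin wounds with the SureCell whole transcriptome 3' kit on the ddSeq droplet system, per the labels' protocols. The 6 libraries fall into 2 groups of 3 by their titles, CD11b and CD11b with F4/80, and the replicate numbers 1 to 3 come from the same titles. The deposited tables hold whole-number UMI counts per gene and cell barcode, not normalized. The genome build was mm9, and FastQC and Seurat are named without role or version, per the submitters' processing notes. The aligner, the counting tool, the annotation and the rule by which barcodes were preselected are not given in the sources used here. Replicate 1 of each sort is a table of 144 or 148 preselected barcodes, and replicates 2 and 3 are lists of 78307 to 136718 barcodes, so the authors' processing differed between them in that respect. No mitochondrial genes are listed in the tables, so the filter of 20% mitochondrial counts removed nothing. Gene symbols were used as the tables give them, 24421 in all, and older symbols were matched in the gene lists (Irg1 for Acod1). No genomic coordinates are given, because the reference at hand was of another build.

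Barcodes with at least 200 detected genes were kept as cells, 922 in all. UMI counts were divided by each cell's total, scaled to 10000 and log-transformed. Cells were clustered in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3) on 2000 variable genes, 20 principal components and 15 neighbours with the Leiden method (leidenalg 0.10.2, resolution 1.0, seed 0). A cluster was named X-like by the list with the most markers that were found in at least 10% of its cells and at least 1.5-fold above the other cells, with at least 3 markers needed. The 20 marker lists covered macrophages, monocytes, neutrophils, dendritic cells, Langerhans cells, plasmacytoid dendritic cells, T, NK and B cells, mast cells, basophils, eosinophils and 8 types of skin, muscle, fat and blood cells that a sort could carry over. Macrophage-like and monocyte-like clusters together formed the mononuclear phagocyte-like class. Doublets were called with Scrublet, 69 cells or 7.48%, and were kept. Top genes of clusters were ranked by fold with 50 CPM added.

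UMI counts were summed per library, over all kept cells or over a class, since cells are not replicates. A class sum needed at least 10 cells, which left out CD11b replicate 3 for phagocyte-like cells. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM composition factors, filterByExpr by group) in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05, and the 2 classes within libraries with the library as a block. The 16 gene lists and the marker lists were tested by camera in limma 3.58.1 with a preset correlation of 0.01, with fry run beside it, and again with an estimated correlation. Between the classes the lists were tested and summed without genes that mark either class. CPM of single genes are scaled by the TMM factors unless called plain. List sums, levels given with the test between sorts and classes, and levels compared with near-empty barcodes are plain CPM. Shares and list sums were compared by two-sided exact permutation tests of library values. Shares of single libraries have exact (Clopper-Pearson) 95% intervals. A fold against a group without UMIs is given against a floor of 3 counts over the whole group, and with 1 to 3 counts the ratio of pooled levels is given with an exact 95% interval. Intervals and floors cover counting error only. In list medians at the bound, genes without UMIs in a group stand at that floor.

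Named genes were chosen by rule. In each comparison between the sorts these are the 8 genes with the largest change in each direction among those with adjusted p under 0.05, mean CPM of at least 50 and no overlap between the groups, without Gm, Rik, ribosomal, mitochondrial or pseudogenes, or the 4 with the smallest p where fewer than 4 pass. Up to 4 members of each described list with the smallest p were added, as were the sort markers Itgam, Adgre1 and Ptprc and a few genes of the series title, among them Tnf, Srebf1 and Srebf2. Results of some genes that this rule names are not reported here. Cluster leaders, genes of the test between sorts and classes and genes of near-empty barcodes are named outside this rule, after their values were seen. The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined.

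Kept cells held 50999 to 655412 UMIs per library, which sets the precision: at 50999 UMIs a gene at 50 CPM has about 3 counts. The test was tested on simulated data drawn from the real means and library sizes with 200 changed genes. Over all kept cells (4013 genes) 74% of 4-fold and 8% of 2-fold changes were recovered with 5 false among 87 calls, and in phagocyte-like cells (5215 genes) 26% and 2% with 2 false among 30. In neutrophil-like cells (949 genes) the shares were 91% and 28% with 5 false among 124 calls, and between the classes (1652 genes) 76% and 20% with 6 false among 102. Counts of replicates of 1 sort differed beyond sampling noise (chi-square per degree of freedom 2.95 to 6.27), so none was taken for a duplicate.

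Alternatives were DESeq2 1.42.0, RLE factors as DESeq2 uses them, no composition factors, no filter on low counts, at least 50 UMIs per gene, the replicate number as a block, each library left out in turn, every barcode, at least 500 genes per cell, called doublets removed, libraries thinned to 1 total, clustering at resolution 0.5 or 2.0 and cells classed singly by marker list. Replicates 2 and 3 alone, no minimum number of cells, a minimum of 5 cells with called doublets removed and the thinning of phagocyte-like sums were added after the data had been seen. Barcodes under the cell filter were used only as every barcode and as a measure of free RNA.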

Results

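Gene expression was measured in single cells from mouse skin wounds. Wounds of 4 mm were punched through the full skin, 8 mm biopsies around them were digested with enzymes, and live cells stained for CD45, F4/80 and CD11b were sorted before a 3' single-cell library was made. CD11b, an adhesion receptor of myeloid cells, is encoded by Itgam, and F4/80, a surface receptor of mouse macrophages, by Adgre1. The titles name 2 sorts of wild-type cells with 3 libraries each: CD11b, and CD11b with F4/80. They are called CD11b and F4/80 libraries here. The series title concerns TNF, SREBP transcription factors of lipid synthesis, macrophage state and repair, but no treatment is given for these 6 libraries, so the comparison the labels imply is between the sorts. Whether the CD11b sort left out cells with F4/80 is not stated, nor is it stated whether the replicates came from separate mice. The p-values therefore measure only the spread between these samples, which may be technical.

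After the cell filter 922 of 440185 barcodes were kept: 126, 150 and 74 cells in CD11b replicates 1 to 3, and 145, 244 and 183 in F4/80 replicates 1 to 3. The tables held 226526, 727037 and 336296 unique molecular identifiers (UMIs, each standing for 1 captured transcript) for the CD11b libraries, of which 220493, 162268 and 50999 lay in kept cells. For the F4/80 libraries the totals were 366786, 1697878 and 1197810, with 365764, 655412 and 405080 in kept cells. Median UMIs per kept cell were 1654.5, 1009 and 670 in the CD11b libraries and 1917, 1908 and 1709 in the F4/80 libraries. Replicate 1 of each sort held only 144 and 148 preselected barcodes, and the others held 78307 to 136718. The table layout may therefore act as a batch, and the main fits between the sorts held no term for it. Values from replicates 2 and 3 alone, a check added after the data had been seen, stand beside some of the main ones.

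The first question was which cells each sort held. The CD11b libraries were mostly neutrophil-like cells, the short-lived granulocytes of early wounds, and the F4/80 libraries mostly mononuclear phagocyte-like cells, the class that takes in monocytes, macrophages and dendritic cells. Neutrophil-like cells were 92.8% ± 2.82 (SD, n = 3) of kept cells in the CD11b libraries and 15.6% ± 7.61 in the F4/80 libraries. Per library the shares were 90.5% (95% exact binomial interval 84.0 to 94.98), 92.0% (86.4 to 95.8) and 95.9% (88.6 to 99.2) against 6.90% (3.36 to 12.3), 19.3% (14.5 to 24.8) and 20.8% (15.1 to 27.4). Macrophage-like cells made up 0.751% ± 0.797 and 50.5% ± 16.1, and monocyte-like cells 6.44% ± 2.09 and 33.8% ± 9.55. The sorts did not overlap for any of these classes. A two-sided exact permutation test gave p = 0.1 for each, the smallest p that 3 against 3 libraries allow, and 0.1 after Benjamini-Hochberg adjustment. In replicates 2 and 3 alone the neutrophil-like shares were 94.0% ± 2.79 and 20.01% ± 1.06. Among cells with at least 500 genes, CD11b replicates 1 and 2 were 81.0% (68.6 to 90.1) and 57.1% (28.9 to 82.3) neutrophil-like and replicate 3 had no cells, against 12.4% ± 6.72 (SD, n = 3) in the F4/80 libraries. Cells called as doublets, which were kept, made up 11.1%, 18.7% and 20.3% of the CD11b libraries and 3.45%, 1.64% and 1.64% of the F4/80 libraries. The sort itself, the lower depth of the CD11b libraries and the filter of 200 genes per cell can all set such shares.

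**Figure D1:**
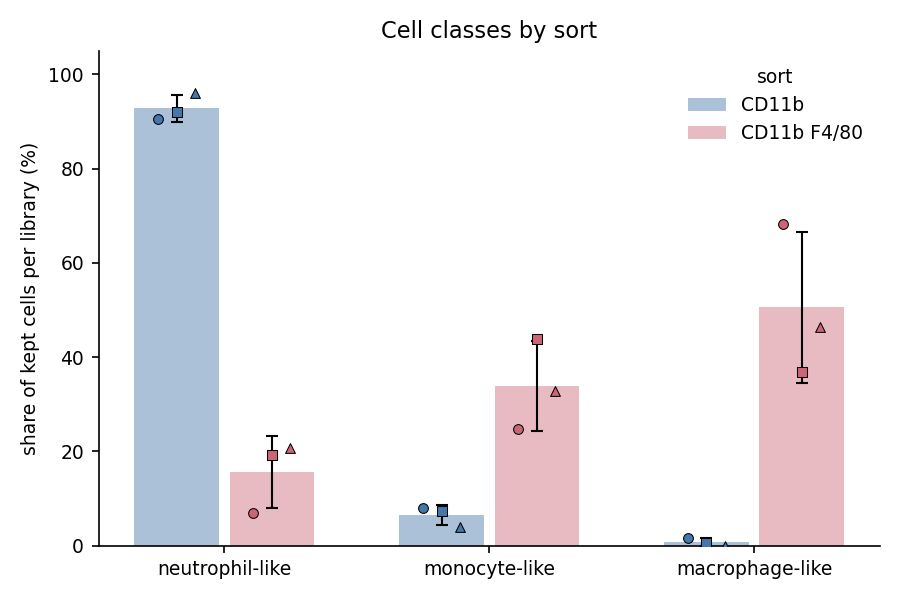
Share of kept cells (percent) in each cell class by sort, with bars at the mean, error bars of 1 SD and a point per library (circle, square and triangle for replicates 1, 2 and 3). Neutrophil-like cells averaged 92.8% of the CD11b libraries and 15.6% of the F4/80 libraries.

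The classes rested on 7 clusters. Of these, 3 were neutrophil-like (147, 144 and 127 cells). Cluster 0 (155 cells) was monocyte-like, with Plac8, Ly6c2, Ccr2, Chil3 and Ms4a4c among its top 10 genes. The cluster also had H2-Ab1, H2-Eb1, H2-Aa, Cd74 and H2-DMb1, of MHC class II antigen presentation, in that top 10. It held 19 of the 24 monocyte-like cells of the CD11b libraries, so their share of monocyte-like cells takes in cells that a finer clustering, given below, called dendritic cell-like. Cluster 2 (146 cells) was macrophage-like, led by Ccl7, Cbr2, Ccl8 and C1qb. Cluster 4 (131 cells) was macrophage-like by 3 markers, among them Csf1r and Trem2, with Lpl, Mmp12 and Itgax in the lead and none of its markers among its top 10. Cluster 6 (72 cells) was monocyte-like by Vcan, Fn1 and F10, with 2 macrophage markers raised as well. It was led by Serpinb2, Arg1, Nos2 and Ereg, and had a median of 5569.5 UMIs per cell.

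Over all kept cells, the F4/80 libraries were higher for genes of macrophages, complement, lysosomes and repair, and the CD11b libraries for neutrophil genes and cytokines. C1qb, a chain of the complement C1q complex that macrophages make, had no UMI in the CD11b libraries against 2232 UMIs in the F4/80 libraries, at least 194-fold higher when 3 counts over the group are taken as the floor. In the other direction S100a9, a calcium-binding alarmin of neutrophils, was at 45319.7 ± 10975.5 CPM (UMIs relative to the library total, SD, n = 3) in the CD11b libraries and 3812 ± 769 in the F4/80 libraries, a log2 change of -3.57 ± 0.27 (SE). Of 4013 genes tested with edgeR, 688 were higher and 542 lower in the F4/80 libraries at an adjusted p under 0.05, with 1664 at an unadjusted p under 0.05, and DESeq2 called 700 and 447. Library values did not overlap between the sorts for 1862 genes (46.4%). Chance gives 10% for libraries of like depth, and the CD11b sums were shallower. With no composition factors the split was 1157 higher and 359 lower, 76.3% higher against 55.9%. The median log2 change of all genes was 0.16, and it was 0.27 with DESeq2's size factors and 0.57 with no composition factors. With replicates 2 and 3 alone there were 589 and 444 genes, 855 of these 1033 shared with the main result.

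The genes with the largest rises included C1qa, another C1q chain (at least 90.7-fold higher), Mmp19, a matrix metalloproteinase (at least 74.7-fold, at 647 ± 249 CPM in the F4/80 libraries), Lyz1, a lysozyme (at least 56.0-fold), Cbr2, a carbonyl reductase (at least 30.8-fold), Pmp22, a myelin and membrane protein (at least 25.01-fold) and Capn2, a calcium-dependent protease (at least 19.9-fold). The monocyte-attracting chemokine Ccl7 had 1 UMI in the CD11b libraries, and its ratio of pooled levels was 491 (95% counting interval 88.0 to 19399). Genes with the largest falls were BC100530 and Stfa2, of the stefin family of protease inhibitors, whose near-identical copies leave their counts uncertain (BC100530 2 UMIs in the F4/80 libraries, ratio 0.00531, interval 0.000633 to 0.0198; Stfa2 -5.64), and Lcn2, an iron-sequestering granule protein (-4.13 ± 0.33). The MHC class I-like gene H2-Q10, the chemoattractant Prok2, the glucose transporter Slc2a3 and the methionine sulfoxide reductase Msra followed, with log2 changes of -3.86, -3.85, -3.82 and -3.78. Fam101b was the last of the 8, at -3.75.

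The sort marker Adgre1 was at 31.1 ± 35.2 CPM in the CD11b libraries and 224 ± 76.9 in the F4/80 libraries (log2 change 2.58 ± 0.54, edgeR adjusted p = 0.0016). Itgam was at 506 ± 163 and 751 ± 197 CPM (0.52 ± 0.30, adjusted p = 0.21), and passed only with no composition factors (0.90, adjusted p = 0.013). Ptprc, which encodes CD45, fell by 1.24 ± 0.27 on the log2 scale (adjusted p = 0.0021). Tnf, the cytokine of the series title, was at 1092 ± 364 CPM in the CD11b libraries and 336 ± 27.3 in the F4/80 libraries (-1.72 ± 0.29, adjusted p = 0.00026).

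**Figure D2:**
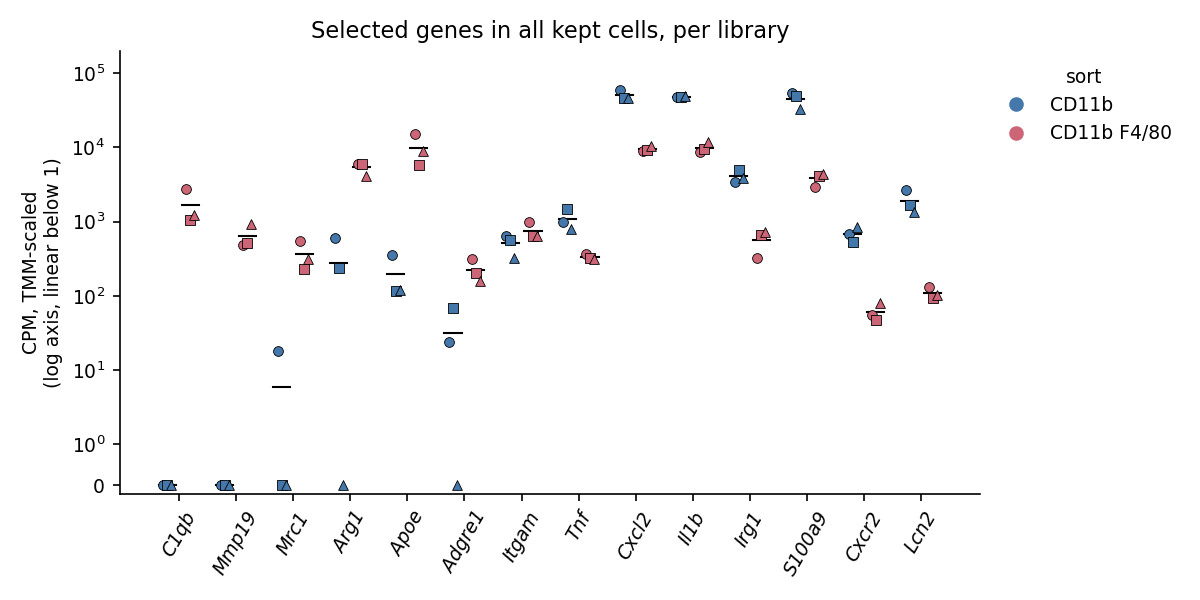
Expression of 14 named genes over all kept cells, in CPM scaled by composition factors on a log axis that is linear below 1, with a point per library (circle, square and triangle for replicates 1, 2 and 3) and a line at each sort's mean. C1qb was at 0 in the 3 CD11b libraries, and S100a9 averaged 45319.7 CPM there and 3812 CPM in the F4/80 libraries.

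Gene lists moved with the cell classes, and each change below goes together with the shift in neutrophil-like share from 92.8% to 15.6%. Of 14 tested macrophage markers 13 were higher and 0 lower (median log2 change 5.43, or 4.54 with genes at 0 set to their bound, camera adjusted p = 1.24e-08, and 0.396 with an estimated correlation). Trem2, a lipid-sensing receptor, rose by 4.79 ± 0.56 and Apoe, a lipid carrier, by 5.53 ± 0.45. The scavenger receptor Stab1 had 1 CD11b UMI, with a pooled ratio of 72.2 (12.9 to 2861). Of 13 neutrophil markers all 13 were lower (median -3.39, adjusted p = 3.28e-13, and 0.34 with an estimated correlation), among them the chemokine receptor Cxcr2, at 687 ± 158 CPM against 60.8 ± 17.8. Of 9 monocyte markers 6 were higher, 7 when adjusted over the list alone (median 1.06, 0.86 to 1.70 with each library left out, adjusted p = 0.033, and 0.531 with an estimated correlation), with Vcan, a proteoglycan, at 3.81 and Ccr2, the receptor for Ccl2, at 2.12 ± 0.52. The monocyte call was lost without CD11b replicate 2 (adjusted p = 0.098) or 3 (0.059). None of 6 dendritic cell markers passed (median 0.46, 0.14 to 0.88 with each library left out, camera adjusted p = 0.424), with 0 when adjusted over the list alone. They included H2-Aa at 0.58 (adjusted p = 0.16) and Cd74 at 0.45 (adjusted p = 0.26).

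Cytokine and granule lists were lower in the F4/80 libraries. Of 29 genes of the TNF and NF-kB response 17 fell and 0 rose, 18 when adjusted over the list alone (median -1.16, camera adjusted p = 7.84e-07, and 0.396 with an estimated correlation). Cxcl2, a neutrophil-attracting chemokine, was at 50320 ± 7277 CPM in the CD11b libraries and 9458 ± 719 in the F4/80 libraries (-2.41 ± 0.23). The inflammatory cytokine Il1b was at 48203.5 ± 1084 and 9934 ± 1523 CPM (-2.28 ± 0.23), Irg1, the enzyme that makes itaconate, fell by 2.85 ± 0.32, and Il23a, a subunit of interleukin 23, by 3.54 ± 0.47. Of 10 neutrophil granule genes 7 fell and 2 rose, 3 rising when adjusted over the list alone (median -1.87, adjusted p = 0.00267, and 0.396 with an estimated correlation). The gelatinase Mmp9 fell by 2.53 ± 0.43. The granule sum did not fall without Lcn2 and Mmp9, which also mark neutrophils: it was 2461 ± 791 CPM in the CD11b libraries and 3411 ± 433 in the F4/80 libraries (SD, n = 3, two-sided exact permutation p = 0.3).

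Lists of repair, lysosome and complement genes were higher. Of 16 genes of alternative activation and repair 13 rose and 0 fell (median 3.09, or 2.73 at the bound, adjusted p = 1.98e-05, and 0.407 with an estimated correlation). Arg1, the arginase that serves as a mark of this state, rose by 4.10 ± 0.54 (277 ± 298 against 5413 ± 1082 CPM), and Mrc1, the mannose receptor, had 3 CD11b UMIs and a pooled ratio of 38.1 (13.0 to 185). Of 22 lysosome genes 19 rose and 1 fell (median 1.52, adjusted p = 1.26e-05, and 0.407 with an estimated correlation), including the proteases Lgmn (4.34 ± 0.45) and Ctss (2.77 ± 0.34). Of 15 complement and scavenging genes 9 rose and 2 fell, 9 and 4 when adjusted over the list alone (median 3.92, or 3.25 at the bound, adjusted p = 0.00619, and 0.407 with an estimated correlation), with Cd36, a scavenger receptor for lipids, at a pooled ratio of 125 (34.5 to 1034) over 2 CD11b UMIs. Of 16 chemokine genes 9 rose and 2 fell, 9 and 3 when adjusted over the list alone (median 1.79, 1.73 to 3.23 with each library left out, adjusted p = 0.0495, lost with DESeq2's size factors at 0.060, and 0.407 with an estimated correlation). The chemokine Pf4 rose by 5.82 ± 0.62. Of 24 genes of oxidative phosphorylation 10 rose and 0 fell (median 0.98, adjusted p = 0.0116, lost in replicates 2 and 3 alone at 0.062, and 0.503 with an estimated correlation), with Cox7c of complex IV at 2.02 ± 0.47.

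The remaining lists did not pass as lists by camera. By fry, matrix and protease genes (fry adjusted p = 0.0331) and the LXR targets given below (0.0101) were higher, and monocyte markers were not called (0.0533). The interferon response had 3 higher and 6 lower of 24 genes (median -0.26, camera adjusted p = 0.0904), with the exonuclease Isg20 falling by 2.72. Of 20 matrix and protease genes 10 rose and 3 fell (0.98, adjusted p = 0.0652). Fn1, fibronectin, rose from 133 to 3995 ± 750 CPM (4.63 ± 0.53). Of 19 genes of glycolysis and hypoxia 2 fell, 1 when adjusted over the list alone (-0.28, adjusted p = 0.0699), among them the lactate exporter Slc16a3 at -1.94 ± 0.27. Of 24 immediate early and heat shock genes 3 rose and 8 fell (-0.33, adjusted p = 0.101), and of 3 cell cycle genes 1 fell (-0.70, adjusted p = 0.161). Of 8 genes of MHC class II presentation 2 rose, 3 when adjusted over the list alone (0.69, adjusted p = 0.0981). H2-Ab1, a chain of the class II molecule, was at 0.79 ± 0.30 (adjusted p = 0.055), and passed under 10 of the alternative settings. With each library left out the medians were -0.52 to -0.06 for interferon, -0.45 to -0.01 for glycolysis, -0.42 to -0.21 for immediate early, -0.85 to -0.39 for cell cycle and 0.34 to 0.88 for MHC class II genes.

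Markers of 5 other cell types were measured by 1 or 2 genes each. Cd24a (-2.16) and Ltc4s (3.73) of the Langerhans cell list passed in opposite directions, Tcf4 of the plasmacytoid dendritic cell list was at 1.44, Il7r of the T cell list at 2.14, and Acta2 of the pericyte list at -1.74. Klrd1 of the NK cell list had 22 UMIs in the CD11b libraries and 3 in the F4/80 libraries, a pooled ratio of 0.0319 (0.00611 to 0.106). By edgeR, Tcf4 no longer passed without any 1 of the CD11b libraries or F4/80 replicate 3 (highest adjusted p 0.0804), Il7r without CD11b replicate 2 (0.097) or F4/80 replicate 2 (0.0931), and Acta2 without CD11b replicate 1 (0.214) or 2 (0.0753). Without any 1 of the F4/80 libraries Acta2 and Klrd1 were not tested, nor was Klrd1 without CD11b replicate 2. The other 11 marker lists, for B cells, mast cells, basophils, eosinophils, fibroblasts, keratinocytes, endothelial cells, melanocytes or Schwann cells, skeletal muscle, adipocytes and erythroid cells, had no gene tested over all kept cells.

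SREBP targets were examined because of the series title, and most were too sparse to test. Srebf1, which encodes SREBP1, was at 33.7 ± 5.81 CPM in the CD11b libraries and 34.5 ± 7.75 in the F4/80 libraries (0.09 ± 0.60, edgeR adjusted p = 0.93). Srebf2, which encodes SREBP2, had 43 UMIs and was not tested. The list of cholesterol synthesis and uptake, with 3 genes tested, had a median of 0.39 (0.29 to 0.66 with each library left out, camera adjusted p = 0.686). Of its members Msmo1, a sterol oxidase, was at -0.85 ± 0.56 (adjusted p = 0.27) and Ebp at 0.39 ± 0.56 (adjusted p = 0.63). Of 5 fatty acid synthesis genes 2 rose, also when adjusted over the list alone (median 0.74, 0.41 to 2.19 with each library left out, adjusted p = 0.336): Acly, which makes cytosolic acetyl-CoA (2.42 ± 0.68), and Scd2, a fatty acid desaturase (1.86 ± 0.58). Without CD11b replicate 2 they were at 1.73 (adjusted p = 0.063) and 1.42 (adjusted p = 0.10), and Scd2 also did not pass without F4/80 replicate 2 (adjusted p = 0.075). Of 9 genes listed as LXR targets of cholesterol efflux 4 rose (median 1.07, 0.71 to 1.63 with each library left out, camera adjusted p = 0.0632). Among them were Pltp at 3.99 ± 0.52 and the cholesterol exporter Abca1 at 1.42 ± 0.35. Not all of the listed genes export cholesterol (Lpl is a lipase), so the list does not measure efflux itself.

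Summed over each whole list, a measure added after the genes had been tested singly, cholesterol synthesis and uptake took 260 ± 47.8 CPM (SD, n = 3) in the CD11b libraries and 409 ± 88.9 in the F4/80 libraries (two-sided exact permutation p = 0.2). Fatty acid synthesis took 136 ± 58.3 and 436 ± 75.2 CPM, and LXR targets 742 ± 88.0 and 12106 ± 4252 CPM (exact permutation p = 0.1 each, the smallest possible). Most of the LXR sum was Apoe, a macrophage marker here, and without it the sum was 581 ± 19.6 and 2125 ± 185 CPM (exact permutation p = 0.1). The 2 SREBP sums rested on 711 and 714 UMIs over the 6 libraries.

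The next question was whether the phagocyte-like cells themselves differed between the sorts. CD11b replicates 1 and 2 held 12 such cells each, and replicate 3, with 3 cells, was left out, against 135, 197 and 145 cells in the F4/80 libraries. Of the CD11b cells 3, 5 and 3 were called doublets, 11 of 27, against 8 of 477 in the F4/80 libraries. Genes of macrophages, complement and lysosomes were higher in those of the F4/80 libraries, and genes of dendritic cells and MHC class II were higher in those of the CD11b libraries. C1qb had no UMI in the CD11b cells against 2208 ± 1126 CPM (SD, n = 3), at least 43.8-fold higher. The decoy receptor of interleukin 1, Il1r2, fell from 2191 ± 1089 to 164 ± 28.0 CPM (log2 change -3.72 ± 0.46, edgeR adjusted p = 2.68e-08). Il1r2 is also on the neutrophil marker list. In barcodes with fewer than 10 genes it was at 7130 and 6340 plain CPM in CD11b replicates 2 and 3. In F4/80 replicates 2 and 3 it was at 1213 and 1158 plain CPM there. Neutrophil RNA in the CD11b droplets was not tested as its source. Of 5215 genes 79 were higher and 32 lower, with 907 at an unadjusted p under 0.05, and DESeq2 called 57 and 49. Library values did not overlap for 2330 genes (44.7%). Chance gives 20% only for libraries of like precision, and the CD11b sums of 12 cells each are noisier, so these shares cannot be compared. With no composition factors 50 were higher and 40 lower, 55.6% higher against 71.2%. The median log2 change of all genes was 0.53, 0.40 with DESeq2's size factors and 0.22 with no composition factors, so values here are read relative to it. Different clusters held the cells. Cluster 0 took 6 of 12, 10 of 12 and 3 of 3 of the CD11b phagocyte-like cells and 18.5%, 36.04% and 27.6% of those in the F4/80 libraries, while cluster 2 took 56.3%, 19.8% and 20.7% in the F4/80 libraries.

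Of 41 named genes that passed, 13 passed also with each of the 5 libraries left out in turn, where leaving out CD11b replicate 1 or 2 leaves 1 CD11b library that is assumed to vary like the others. These were the C1q chains C1qa (at least 20.6-fold higher), C1qb and C1qc (at least 26.3-fold), Ccl7 (at least 43.6-fold), Mmp19 (at least 17.1-fold), Lyz1 (at least 12.5-fold), Timp2, an inhibitor of metalloproteinases (at least 8.96-fold), Cd36 (2 CD11b UMIs, pooled ratio 28.5, interval 7.88 to 236), the chemokine Ccl6 (3.80 ± 0.59), the lysosomal proteases Ctsb (3.41 ± 0.50) and Ctsd (3.24 ± 0.50), Il1r2 and Pxdc1. Pxdc1, which also leads the dendritic cell-like cluster described below, was at 781 ± 367 CPM in the CD11b cells and 18.5 ± 3.14 in the F4/80 cells. Other lower genes were less stable, such as Flt3, a growth factor receptor of dendritic cells (-4.85 ± 0.77), the peptidase Dpp4 (-4.04) and the stem cell factor receptor Kit (-4.45), the 1 tested mast cell marker, which without CD11b replicate 2 had adjusted p of 0.289, 0.399 and 0.289. Without F4/80 replicate 1, 2 or 3 the counts were 40, 22 and 13 higher, and without CD11b replicate 1 they were 229 higher and 67 lower. Without F4/80 replicate 2 or 3 the lower genes were 14 and 9. With called doublets removed and at least 5 cells per library (9 and 7 CD11b cells) there were 49 higher and 12 lower genes, 52 of these 61 shared with the main result. Of the 13 genes 12 passed again, with Il1r2 at -2.99, and Pxdc1 was not tested. Replicates 2 and 3 alone left 1 CD11b library against 2, assumed to vary like the others, and gave 389 and 125 genes, of which 97 were shared with the main result.

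Lists gave the same outline. Of 14 macrophage markers 11 were higher, 13 when adjusted over the list alone (median log2 change 4.00, or 2.59 at the bound, camera adjusted p = 2.38e-05, and 0.381 with an estimated correlation). Adgre1 was among them (at least 5.85-fold, edgeR adjusted p = 0.0036), though it did not pass without F4/80 replicate 2 (0.056) or 3 (0.10). Of 22 lysosome genes 9 rose, 12 over the list alone (1.38, adjusted p = 0.00267, and 0.31 with an estimated correlation), and of 15 complement and scavenging genes 6 rose, 10 over the list alone (2.10, or 1.79 at the bound, adjusted p = 0.00213, and 0.381 with an estimated correlation). Of 17 genes of alternative activation and repair 9 rose, 11 over the list alone (2.64, or 1.84 at the bound, adjusted p = 0.00493, and 0.381 with an estimated correlation), with Arg1 at 1.84 ± 0.43 and Spp1, the matrix protein osteopontin, at 2.26 ± 0.48. Neither gene passed without F4/80 replicate 2 (0.251 and 0.167) or 3 (0.254 and 0.208), nor did Arg1 without F4/80 replicate 1 (0.0529) or Spp1 without doublets (0.0955). Of 10 genes of MHC class II presentation 5 fell, 7 over the list alone (-1.43, adjusted p = 6.86e-08, and 0.31 with an estimated correlation), and of 7 dendritic cell markers, which share H2-Aa, H2-Ab1, H2-Eb1 and Cd74 with that list, 6 fell, 7 over the list alone (-1.69, adjusted p = 8.11e-07, and 0.31 with an estimated correlation). H2-Eb1, a class II chain, was at 13968.5 ± 563 CPM in the CD11b cells and 4319 ± 286 in the F4/80 cells (-1.69 ± 0.36), and did not pass without F4/80 replicate 2 (0.166) or 3 (0.194) or without doublets (0.276). None of 3 cell cycle genes passed, with 2 lower when adjusted over the list alone, and the list was lower (-1.55, camera adjusted p = 0.00235, and 0.31 with an estimated correlation). The list of 10 neutrophil markers was called lower (adjusted p = 0.0282, and 0.31 with an estimated correlation) with a median of 0.02 and a mean of 0.21, both below the 0.53 of all genes. Without CD11b replicate 1 the calls of alternative activation (0.29), lysosome (0.087), cell cycle (0.076) and neutrophil markers (0.15) were lost, and without CD11b replicate 2 that of alternative activation (0.059). Medians also moved, and without CD11b replicate 1, where 12 CD11b cells were left, that of all genes was 1.82. With each library left out they were 3.46 to 8.89 for macrophage markers, 2.12 to 6.41 for alternative activation, 1.69 to 8.25 for complement and 1.16 to 2.09 for lysosome genes, each highest without CD11b replicate 1. Those of dendritic cell markers were -2.75 to -1.29 and of MHC class II -1.54 to -0.96. That of cell cycle genes was -0.71 without CD11b replicate 1. In replicates 2 and 3 alone those of alternative activation (0.41), lysosome (0.19), complement (0.051) and cell cycle (0.095) were lost. Without doublets those of alternative activation (0.419), cell cycle (0.0541) and neutrophil markers (0.243) were lost.

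No other list passed by camera in these cells. By fry, which does not set a list against the other genes, 5 more were higher. These were fatty acid synthesis (fry adjusted p = 0.0084), chemokines (0.0097), oxidative phosphorylation (0.0186), matrix genes (0.0284) and LXR targets (0.0324). Neutrophil markers were not called by fry (0.117). Medians with the camera adjusted p were 0.73 (0.92) for monocyte markers, 0.26 (0.505) for the interferon response, 0.42 (0.392) for matrix and proteases, 0.55 (0.957) for glycolysis and hypoxia, 0.70 (0.979) for oxidative phosphorylation, 1.69 (0.167) for chemokines, 0.58 (0.942) for neutrophil granules and 0.02 (0.43) for immediate early and heat shock genes. Most of these medians moved widely with each library left out, over -0.05 to 4.39 for monocyte markers, -0.18 to 1.65 for interferon, 0.20 to 1.82 for matrix, 0.13 to 1.90 for glycolysis, 0.53 to 6.86 for chemokine, 0.25 to 1.73 for granule and -0.46 to 1.33 for immediate early genes, each highest without CD11b replicate 1. The TNF and NF-kB response had 1 higher and 0 lower of 28 genes (-0.15, adjusted p = 0.104), with Tnf itself at -0.61 ± 0.52 (adjusted p = 0.55). With each library left out the list was at -0.43 to 1.54, 1.54 without CD11b replicate 1 where the median of all genes was 1.82. The direction of Tnf turned on 1 library, from -1.34 without CD11b replicate 2 to 2.22 without CD11b replicate 1, with 861 and 101 plain CPM in CD11b replicates 1 and 2. Cholesterol synthesis and uptake had 0 of 7 genes passing (-0.16, adjusted p = 0.299). Fatty acid synthesis had 0 of 5 passing, 1 when adjusted over the list alone (0.23, adjusted p = 0.939), and Srebf1 was at -0.62 ± 1.02 (adjusted p = 0.79), with -1.68 without CD11b replicate 1 and 6.69 without CD11b replicate 2. These medians with each library left out were -0.76 (without CD11b replicate 1) to 1.05 (without CD11b replicate 2) for cholesterol and -0.21 to 1.27 for fatty acid synthesis, so neither had a settled direction. LXR targets had 3 higher of 10 (1.26, or 0.36 at the bound, 0.31 to 6.57 with each library left out, adjusted p = 0.287), among them the lipase Lpl, with 1 CD11b UMI and a pooled ratio of 28.8 (5.14 to 1138). Itgam was at 0.94 ± 0.51 (edgeR adjusted p = 0.31). It had 722 and 252 plain CPM in CD11b replicates 1 and 2 and 954, 708 and 768 in the F4/80 libraries. Ptprc was at -0.59 (edgeR adjusted p = 0.52) and turned to 0.88 without CD11b replicate 1. In this comparison simulated genes of a known 4-fold change were recovered in 26% of cases, and in 72.7% of 22 cases at 200 CPM or more, so changes of that size would mostly be missed in genes of low level.

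At a finer clustering, a resolution fixed beforehand as an alternative, 1 cluster of 54 cells was dendritic cell-like, led by the chemokine Ccl5, the lymph node homing receptor Ccr7, Pxdc1 and MHC class II genes. It held 17 of 27 phagocyte-like cells of the CD11b libraries (63.0%) and 37 of 477 of the F4/80 libraries (7.76%). CD11b replicates 1 to 3 gave 4 of 12, 10 of 12 and 3 of 3 cells. Those of replicate 3 were all called doublets, and that library was not in the gene comparison. Macrophage-like clusters held 2 of 27 (7.41%) and 217 of 477 (45.5%), monocyte-like clusters 8 of 27 (29.6%) and 146 of 477 (30.6%), and unnamed clusters 0 and 77 (16.1%). As a share of all kept cells the dendritic cell-like cluster was 4.63% ± 1.82 (SD, n = 3) and 6.72% ± 1.48 (two-sided exact permutation p = 0.3).

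Neutrophil-like cells of the sorts were compared in turn, to ask whether this class differed between them. Of 949 genes 3 were higher in the F4/80 libraries and 0 lower by edgeR, with 49 at an unadjusted p under 0.05 in either direction, and DESeq2 called 4 and 0. The 3 were Apoe, at 133 ± 16.0 against 981 ± 390 CPM (SD, n = 3; log2 change 2.98 ± 0.40, adjusted p = 0.0024), the cysteine protease Ctss (2.44 ± 0.48, adjusted p = 0.048) and Pf4, with 1 CD11b UMI and a pooled ratio of 100.4 (17.0 to 4062, adjusted p = 0.0026). All 3 are abundant in phagocyte-like cells. Apoe had a UMI in 5.26%, 3.62% and 5.63% of neutrophil-like cells of the CD11b libraries and in 50%, 46.8% and 42.1% of those of the F4/80 libraries, where 88.9%, 81.2% and 84.1% of phagocyte-like cells had one. The neutrophil-like cells had median depths of 1506, 1005 and 668 UMIs in the CD11b libraries and 1723, 1567 and 1515.5 in the F4/80 libraries. Library values did not overlap for 98 genes (10.3%, where chance gives 10% for libraries of like depth).

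Only Apoe passed with each library left out in turn. Ctss still passed without F4/80 replicate 1, which had 10 such cells, and not without any of the other 5 libraries (adjusted p 0.0556 to 0.486). Pf4 was lost without CD11b replicate 1 (0.198) or 2 (0.0915) and was not tested without F4/80 replicate 2. The count of higher genes was 10 without F4/80 replicate 1, with 3 lower, and 1 without CD11b replicate 1, CD11b replicate 2 or F4/80 replicate 2. Replicates 2 and 3 alone gave 2 higher and 1 lower, 2 of them shared with the main result. The genes nearest to a call in the lower direction were Prr13 (-1.37, adjusted p = 0.35), Msra (-1.94, adjusted p = 0.43), Mmp8, a collagenase (-1.33, adjusted p = 0.56), and Glipr2 (-1.48, adjusted p = 0.56). Tnf was at -0.33 ± 0.44 (adjusted p = 0.98), Itgam at -0.14 ± 0.40 and Ptprc at -0.19 ± 0.28, while Adgre1, Srebf1 and Srebf2 had 18, 8 and 25 UMIs and were not tested.

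Of 4 macrophage markers 2 were higher in these cells, 3 when adjusted over the list alone (median log2 change 2.16, camera adjusted p = 2.65e-08, and 0.0747 with an estimated correlation), and of 15 lysosome genes 1 (0.58, adjusted p = 0.0493, and 0.569 with an estimated correlation). The same 4 MHC class II genes made up the tested dendritic cell markers and the antigen presentation list, with none passing, 3 when adjusted over the list alone (1.76, adjusted p = 0.0776). The other lists had medians with the camera adjusted p of -0.01 (0.742) for 22 TNF and NF-kB genes, -0.25 (0.239) for 13 neutrophil markers and -0.49 (0.0776) for 8 interferon genes. Median log2 changes without a call were 0.01 for 4 monocyte markers, -0.04 for 8 matrix genes, 0.09 for 14 glycolysis genes, -0.21 for 3 genes of oxidative phosphorylation, -0.11 for 5 complement genes, 0.06 for 7 chemokine genes, -0.59 for 7 granule genes and 0.01 for 17 immediate early genes.

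The classes were then compared within libraries, to ask in which cells the genes of the series title were expressed. In the 5 libraries with at least 10 cells of each class, TNF response genes were higher in neutrophil-like cells, and MHC class II, lysosome and respiratory genes in phagocyte-like cells. Of 1652 genes 326 were higher and 247 lower in phagocyte-like cells, with 723 at an unadjusted p under 0.05. The classes were defined by expression, so single genes that define them are no result. Other genes of the tested lists were not kept out of the clustering, and some led clusters. Ccl3, Ccl4 and Il23a were top genes of cluster 1, and Irg1 of cluster 5. H2-Ab1, H2-Eb1, H2-Aa, Cd74 and H2-DMb1 were top genes of cluster 0. The p-values between classes, here and below, thus compare groups built from expression in the same cells. They describe the classes and are no independent test. Of 25 genes of the TNF and NF-kB response 15 were lower and 0 higher, 16 when adjusted over the list alone (median log2 change -1.33, camera adjusted p = 2.25e-06, and 0.64 with an estimated correlation). Cxcl2 was at 7935 ± 4311 CPM in phagocyte-like and 57923 ± 10924 in neutrophil-like cells (SD, n = 5, -3.01 ± 0.34), and Irg1 fell by 4.34 ± 0.39. Tnf itself was at -1.32 ± 0.53 (edgeR adjusted p = 0.058) and was higher in the phagocyte-like cells of 2 of 5 libraries. Summed over the list, the TNF genes took 34335 ± 13758 and 131639 ± 12515 CPM, lower in phagocyte-like cells in each of the 5 libraries (two-sided exact permutation p = 0.0625, the smallest possible).

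All 8 MHC class II genes were higher in phagocyte-like cells (median 4.34, camera adjusted p = 7.66e-05, and 0.64 with an estimated correlation), as were 12 of 18 lysosome genes (1.30, adjusted p = 0.00197, and 0.64 with an estimated correlation), among them Ctss (3.78 ± 0.44) and Npc2, which moves cholesterol out of lysosomes (2.74 ± 0.42). Of 14 genes of oxidative phosphorylation 5 were higher, 6 when adjusted over the list alone (1.07, adjusted p = 0.0312, and 0.701 with an estimated correlation), such as Atp5b of the ATP synthase (2.17 ± 0.52), a call lost without F4/80 replicate 1 (0.053), 2 (0.067) or 3 (0.079). With replicates 2 and 3 alone 206 genes were higher. By fry, TNF response (fry adjusted p = 0.0240), MHC class II (0.0240) and lysosome genes (0.0353) were called in the same directions. Oxidative phosphorylation was not called by fry (0.0907), while LXR targets (0.0326), alternative activation (0.0240) and matrix genes (0.0240) were higher. Counts of higher and lower genes, with the median and the camera adjusted p, were 2 and 0 of 4 for LXR targets (1.59, 0.147), 1 and 3 of 11 for interferon (0.41, 0.676), 2 and 0 of 4 for alternative activation (0.92, 0.312) and 4 and 2 of 10 for matrix genes (0.97, 0.323). They were 0 and 1 of 16 for glycolysis (-0.23, 0.378), 3 and 3 of 7 for complement (-1.05, 0.883, mean 0.39), 4 and 1 of 7 for chemokines (1.94, 0.676), 2 and 2 of 5 for granules (0.53, 0.883, mean -0.54) and 4 and 6 of 22 for immediate early genes (-0.07, 0.676, mean 0.21). The interferon mean was -0.12, so median and mean differed in sign there too. Medians of interferon (-0.06 to 0.69), complement (-1.32 to 1.90) and granule genes (-0.81 to 0.58) turned in sign with a library left out, those of matrix genes were 0.65 to 2.71, and those of alternative activation 0.77 to 1.75.

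The SREBP lists had too few tested genes for a list test here. Scd2 was at 179 ± 64.1 CPM in phagocyte-like and 9.70 ± 14.2 in neutrophil-like cells (SD, n = 5, log2 change 3.91 ± 0.80, edgeR adjusted p = 0.0007). Summed, fatty acid synthesis genes took 448 ± 89.9 CPM in phagocyte-like and 134 ± 91.2 in neutrophil-like cells, higher in 5 of 5 libraries, and LXR targets without the marker Apoe 1882 ± 660 and 518 ± 219, also higher in 5 of 5 (two-sided exact permutation p = 0.0625 each). Cholesterol synthesis and uptake took 444 ± 155 and 257 ± 84.9 CPM, higher in phagocyte-like cells in 4 of 5 libraries (exact permutation p = 0.188).

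**Figure D3:**
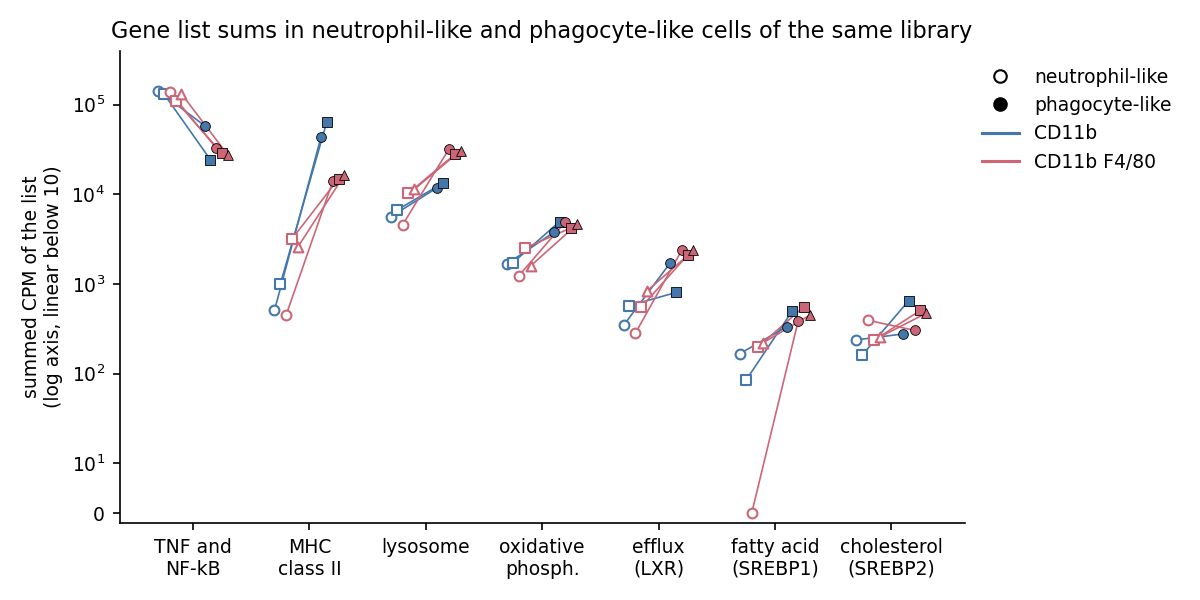
Summed CPM of 7 gene lists, without genes that mark the classes, in neutrophil-like cells (open points) and phagocyte-like cells (filled points) of the same library, on a log axis that is linear below 10, with lines that join the classes of each of 5 libraries. Fatty acid synthesis and LXR targets lay higher in phagocyte-like cells in all 5 libraries, and TNF response genes lower in all 5.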

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

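The tests of TNF genes inside each class, of free RNA, of mixed droplets and of other splits of the libraries were chosen only after the results were seen, while those of cell makeup and depth were set before. The limits for genes in near-empty barcodes were also set after their values were seen.

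Replicates 2 and 3 listed barcodes with fewer than 10 genes, 105643 and 74392 in the CD11b libraries and 131408 and 109435 in the F4/80 libraries, which entered the comparison of sorts only in the alternative with every barcode. In each of these 4 libraries 3 genes with at least 1000 CPM were at least 2-fold above the kept cells. Slfn4, a myeloid gene of the Schlafen family, averaged 6306 CPM there and 2129 CPM in kept cells, the nuclear RNA Neat1 3884 and 1055 CPM, and Vmp1, a membrane protein of autophagy, 1667 and 646 CPM.

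The difference between phagocyte-like and neutrophil-like cells itself differed between the sorts for 12 genes, by edgeR's test of the interaction at an adjusted p under 0.05 (135 genes at an unadjusted p under 0.05). The log2 level in phagocyte-like minus neutrophil-like cells was higher in the F4/80 libraries for 4 genes and lower for 8. Levels here are plain CPM, so they differ from the scaled ones above. Il1r2 was at 2543 CPM in phagocyte-like cells of the CD11b libraries and 142 CPM in those of the F4/80 libraries, but at 4268 and 4743 CPM in neutrophil-like cells (interaction -3.93, adjusted p = 0.0015). Ifitm1, an interferon-induced membrane protein, was at 2967 and 174 CPM against 2194 and 2574 CPM, and Ccl6 at 253 and 2846 CPM against 1546 and 1392 CPM. The others were Nr4a3, H2-Ab1, Mmp12, Ctsd, Spp1, H2-Aa, Hmox1, Mt2 and Emp1. The phagocyte-like side rests on 2 CD11b libraries of 12 cells each, of which 3 and 5 were called doublets. The neutrophil-like side is near the floor for some genes. In the CD11b and F4/80 libraries it held 0 and 19 UMIs of Mmp12, 1 and 14 of Mt2, and 2 and 30 of Emp1. Emp1 was at 1974 and 1743 CPM in phagocyte-like cells, so its call comes mainly from those few counts. Free RNA from phagocytes was not tested for these genes.

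The fall of TNF and NF-kB response genes over all cells had a median log2 change of -1.16, or -1.32 relative to the median of all genes. A change inside neutrophil-like cells is argued against by a relative median of -0.00922 there (95% bootstrap interval over genes -0.22 to 0.20, and -0.24 to 0.17 with each library left out). One inside phagocyte-like cells stays open, with -0.69 (-1.01 to -0.45, and -1.07 to -0.28 with each library left out) against a limit of -0.66, 50% of the fall. After thinning the median was -1.35, past 50% of the observed fall, over 20 of the 29 members, which were at -1.56 before. Thinning of sums keeps expected ratios, so it could hardly have shown otherwise. Depth per cell, which also sets the cells kept, was not tested. Class profiles of the F4/80 libraries were mixed by the share of UMIs in each class of the CD11b libraries (83.7% to 96.0% neutrophil-like). This mixture gave -0.84 (-0.88 to -0.68 with each F4/80 library left out) in plain CPM, where the observed median was -0.86. Cell makeup may thus account for most of the fall.

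The genes that differed in phagocyte-like cells had median log2 differences of 3.37 (79 higher) and -2.86 (32 lower). Rebuilding the CD11b profile from the finer clusters of the F4/80 libraries gave 0.27 and -1.20. With each F4/80 library left out it gave 0.26 to 0.36 and -1.18 to -1.14, all under 50% of the observed value. The rebuilt sign was the observed one for 63 of the 79 and 29 of the 32 genes. This cannot weigh the makeup of these clusters, because the genes were selected for large observed differences. Free RNA also differed between the sorts. In near-empty barcodes of replicates 2 and 3 Apoe was at 236 and 203 CPM in the CD11b libraries and 7010 and 7434 in the F4/80 libraries. Such RNA in the F4/80 clusters would shrink the rebuilt difference. Medians after thinning were 2.27 in the 37 higher genes left (2.52 before) and -2.07 in the 8 lower genes left (-1.77 before). As thinning of sums keeps expected ratios, this does not settle the part of depth. The makeup of the clusters or a finer one, free RNA, depth, selection of the called genes, doublets and a difference in state between sorted cells stay open. With called doublets removed and at least 5 cells the counts were 49 and 12, without CD11b replicate 1 they were 229 and 67, and without F4/80 replicate 3 they were 13 and 9.

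Apoe, Pf4 and Ctss were higher in neutrophil-like cells of the F4/80 libraries. If free RNA from phagocytes entered these droplets, the excess over the CD11b libraries, divided by the level in near-empty barcodes, should be like that of other phagocyte genes. In replicates 2 and 3 it was at most 0.166 for Pf4 and Apoe and 0.254 for Ctss, inside the central 95% of 70 other phagocyte genes (-0.02 to 0.51 and -0.03 to 0.54), so free RNA could account for it. A few droplets with mixed cells cannot be told apart from this, since the genes were found in 55.8% to 89.5% of the cells an even spread would give, a range that met the limit set for neither answer. Uptake or true expression by neutrophils was not tested.

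The splits of the libraries were too few for a share under 0.05. For all kept cells 1 of 10 splits, the real one, gave 1230 genes (highest other 0) and 10 lists (highest other 8), and for neutrophil-like cells 3 genes (highest other 0). Between classes 1 of 16 swaps gave 573 genes (highest other 0) and 2 of 16 gave 4 lists (highest other 4).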

How the results depend on the processing

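Replicates 2 and 3 alone, no minimum number of cells, a minimum of 5 with doublets removed and the thinned phagocyte-like sums were chosen after the data had been seen. Over all alternatives, named genes gave 3673 values, of which 3415 kept their side of the threshold (88 of them uncalled with another sign). Of the others 179 lost the call, 73 gained it and 6 turned in sign with a call in the main fit or the alternative. Lists gave 580, with 499 (27 of them uncalled with another sign), 44, 27 and 10. Where no cause is named below, the cause was not tested. Shares kept their direction, with differences in neutrophil-like share of 72.8 to 79.7 points with each library left out, 80.1 with doublets removed and 56.6 with at least 500 genes per cell (69.1% against 12.4%, with no cells left in CD11b replicate 3). Over all kept cells the genes higher and lower (688 and 542) were 1157 and 359 with no composition factors. With at least 500 genes per cell they were 178 and 143, where cells were fewer, CD11b replicate 3 dropped out and the makeup changed. They were 1079 and 1029 with every barcode (more UMIs) and 237 and 210 after thinning (fewer UMIs). With each library left out they were 516 to 718 and 412 to 615. Lists (7 higher, 3 lower) were 0 and 0 with an estimated correlation, 7 lower with no filter on low counts, and 3 to 5 lower with each library left out (5 without CD11b replicate 2, F4/80 replicate 1 or 2).

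In phagocyte-like cells the genes higher and lower (79 and 32) were 50 with no composition factors (40 lower), 48 and 21 with at least 50 UMIs, 389 and 125 in replicates 2 and 3 alone, 49 and 12 with doublets removed and at least 5 cells (fewer cells) and 16 and 9 after thinning (fewer UMIs). Lower genes were 49 with DESeq2, 61 with no filter and 50 with at least 500 genes per cell. With each library left out the counts were 13 to 229 and 9 to 67: 229 and 67 without CD11b replicate 1, 40 higher without F4/80 replicate 1, 22 and 14 without F4/80 replicate 2 and 13 and 9 without F4/80 replicate 3. Lists (4 and 4) were 0 and 0 with an estimated correlation, 1 and 2 in replicates 2 and 3 alone, 2 lower with no minimum number of cells, 2 lower with doublets removed and at least 5 cells, and 2 to 5 each way with a library left out (2 and 2 without CD11b replicate 1). With at least 10 cells, removing doublets, classing cells singly and resolution 2.0 left 0 CD11b libraries with enough cells and were not run. Some values turned in sign where the main fit or the alternative had a call, which the turned value itself need not have. Ccl5 ran from -5.89 to 7.70 over libraries left out (7.70 without CD11b replicate 2). It was at 7.51 with at least 500 genes and 1.83 with doublets removed and at least 5 cells. Ero1l ran from -2.59 to 1.08 (1.08 without CD11b replicate 1) and was at 1.28 in replicates 2 and 3 alone. Ifit1 was at 7.82 with at least 500 genes. The median of neutrophil markers (0.02) turned to -0.10 with RLE factors, -0.34 with no minimum number of cells and -0.75 to 0.13 over libraries left out. The cell cycle list was at 2.72 with no filter, and immediate early genes at -0.46 to 1.33 over libraries left out (1.33 without CD11b replicate 1), with a call in the lower direction without CD11b replicate 2 (-0.41, adjusted p = 0.010).

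In neutrophil-like cells the genes higher and lower (3 and 0) were 8 and 4 with no filter, 1 lower with at least 50 UMIs, 7 lower with at least 500 genes, 1 lower in replicates 2 and 3 alone, and 1 to 10 and 0 to 3 with a library left out (10 and 3 without F4/80 replicate 1, 1 higher without CD11b replicate 1 or 2 or F4/80 replicate 2). Between classes, higher genes (326) were 206 in replicates 2 and 3 alone (fewer libraries), lists (3 and 1) were 0 and 0 with an estimated correlation and 5 and 4 with no filter, and granule genes turned to -1.73 with no filter.

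Deviations of same-numbered libraries correlated at 0.15, 0.04 and 0.12 over 2878 genes, not all over 0.1, so the replicate numbers were not taken to pair them, though each library correlated best with its own number. With the replicate block, genes were 598 and 466 over all kept cells (1022 of 1064 shared), 32 and 5 in phagocyte-like cells (35 of 37 shared) and 4 and 1 in neutrophil-like cells, and the neutrophil marker median in phagocyte-like cells was -0.27. The exact sign-flip permutation p for shares with the block was 0.25, the smallest that 3 pairs allow. Depth limits the phagocyte-like comparison, where CD11b replicates 1 and 2 held 12 such cells each.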

Other observations

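All values here were chosen after the results of the comparisons had been seen. Among phagocyte-like cells of the F4/80 libraries the clusters differed in the programs they expressed, given as summed CPM without genes that mark macrophages, monocytes or neutrophils (mean ± SD over 3 libraries). The genes took part in the clustering, so the values describe the clusters and test nothing. Alternative activation and repair genes were at 27757 ± 6428 CPM in cluster 6, led by Serpinb2, Arg1 and Nos2, against 3440 ± 666 in cluster 0, 9838 ± 2786 in cluster 2 and 13024 ± 2030 in cluster 4. The list had 921, 3898, 2382 and 11916 UMIs in clusters 0, 2, 4 and 6, and Spp1 alone had 7916 in these phagocyte-like cells. Its part in each cluster was not examined. Between the classes Spp1 was at 5221 ± 3572 CPM in phagocyte-like and 7063 ± 4520 in neutrophil-like cells (SD, n = 5), so it does not mark phagocyte-like cells. Cluster 6 also held the most glycolysis and hypoxia genes, 13352 ± 1132 CPM against 4953 ± 606, 5477 ± 1140 and 8411 ± 459 in clusters 0, 2 and 4, and 1704 ± 542 CPM of MHC class II genes against 39429 ± 10638 in cluster 0. Interferon response genes ran from 5199 ± 945 CPM in cluster 0 and 4002 ± 482 in cluster 2 to 2332 ± 423 in cluster 4 and 1421 ± 447 in cluster 6.

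Cholesterol synthesis and uptake was at 717 ± 260 CPM in cluster 0 and 347 ± 76.2, 395 ± 122 and 315 ± 114 in clusters 2, 4 and 6. Fatty acid synthesis was at 468 ± 132, 319 ± 61.7, 512 ± 99.2 and 563 ± 106 CPM in clusters 0, 2, 4 and 6. Apoe gave 7673 of the 8674 UMIs of LXR targets in cluster 2, and without it the list was at 1478 ± 354, 2635 ± 378, 3084 ± 877 and 1815 ± 223 CPM in clusters 0, 2, 4 and 6, so that clusters 2 and 4 overlapped.

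F4/80 replicate 1 stood apart in makeup. At the finer clustering a macrophage-like cluster of 28 cells, led by Ltc4s, Ccl7 and Cbr2 with raised Folr2 and Cd163, markers of resident tissue macrophages, took 27 cells from F4/80 replicate 1, 0 from replicate 2 and 1 from replicate 3. Replicate 1 is also the library with preselected barcodes, so its source and its processing cannot be separated here.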
